A study of Mus musculus with 24 samples.

How the data were processed

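Gene expression was measured on 24 Agilent 1-colour mouse arrays, each hybridised with Cy3-labelled RNA of isolated mouse cardiomyocytes. Per the labels' protocols, mice received doxorubicin at 25 mg/kg or PBS by intraperitoneal injection, hearts were taken 16 h or 72 h later, live cardiomyocytes were isolated on a Langendorff apparatus, and 100 ng of total RNA was amplified and labelled per sample. The 8 groups, each of 3 arrays, combine genotype, treatment and time. Genotype was taken from the sample titles, which 2 further label fields share. The genotype characteristic of 4 arrays at 16 h differs from their titles, namely wild-type PBS replicate 3, wild-type doxorubicin replicate 1, Top2b-deleted PBS replicate 3 and Top2b-deleted doxorubicin replicate 1. The labels do not say that each array is a separate animal, so the p-values measure only the spread between these samples.

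The authors deposited 1 scanner file per array, written by Agilent Feature Extraction 10.7.3.1 per the file headers. Each file holds the processed intensity of every spot on a linear scale, after background subtraction and detrending and with no normalization between arrays, per the file headers. The raw mean intensity, the local background intensity and flags for each spot were deposited beside it. A value table was also deposited. Its values are a linear ratio, the processed signal of the deposited scanner file divided by the median of that array, as found by setting the columns side by side: the log2 difference had an SD of at most 1.5e-06 on any array, and every column had a median of 1. Why the authors divided by the median is not stated in the sources used here. The deposited flags mark outlier spots and spots well above background.

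Each array has 62976 spots, of which 59305 are not controls. These hold 55681 distinct probes with 34844 gene names. By accession 26762 probes matched the RefSeq table, and 31220 had a current symbol by accession, symbol or unique synonym. The gene names of the array files were kept in the text. Between 42.9% and 52.6% of spots were well above background per array, 0 non-control spots were saturated, and 89 to 277 spots per array were outliers and were set to missing. The number of arrays limits the precision of every value.

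The processed signal was converted to log2 and the 75th percentile of each array was subtracted. A probe was kept at a time point if it was well above background on all 3 arrays of at least 1 group. Spots of a probe were averaged, and a gene took its brightest kept probe. This left 18750 genes at 16 h and 19669 genes at 72 h. Where a gene was well above background on every array of 1 group and on none of the other, only a bound was given as at least N-fold. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

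The 4 groups of each time point were fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes, 8 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over genes, with a threshold of 0.05. The comparisons were doxorubicin against PBS in each genotype, Top2b-deleted against wild type in PBS, the difference between the genotypes' doxorubicin responses (Top2b-deleted response minus wild-type response), and doxorubicin against PBS averaged over genotypes. The 2 times were hybridised on different slides, so times and slides cannot be told apart and no test was made between times. Fold changes are log2 differences ± SE with 3 arrays per group.

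Before the data were examined, 35 gene lists were fixed, 25 of pathways and 10 of cell type markers, with 915 entries. Each was tested with limma's camera at a preset correlation of 0.01, against all other genes, adjusted over all lists and comparisons. An estimated correlation was the alternative. Member counts were also adjusted over the list alone. The genes named are the 10 largest rises and 10 largest falls past the threshold in each doxorubicin comparison and each genotype comparison, measured on every array of both groups and with no overlap between groups, 5 per direction for the difference of responses, up to 3 bounded genes per direction, the topoisomerases, and the 4 members of each list with the smallest adjusted p. Some genes that this rule names are not reported here. Other genes named were chosen after their values were seen. The response size is the mean, over genes past the threshold in the averaged comparison, of the wild-type minus the Top2b-deleted response, each turned to the direction of the averaged change. Where an alternative left 0 genes past it, the 200 genes with the smallest p were used. Its p comes from 400 permutations of genotype within treatment, and tests whether genotype matters in either treatment.

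The procedure was tested on simulated data with 200 changed genes. Noise was independent between genes and arrays, and the changes were placed only in wild-type doxorubicin arrays. The real data have other numbers of changed genes and related arrays, so the rates below need not hold for them. Of genes changed 2-fold and 4-fold, it recovered 60% and 92% for the wild-type doxorubicin comparison at 16 h (18750 genes), and 39% and 79% at 72 h (19669 genes). For the difference of responses it recovered 26% and 79% at 16 h, and 9% and 61% at 72 h. Unchanged genes called were 10 at 16 h and 8 at 72 h for wild-type doxorubicin, and 5 and 2 for the difference of responses. Alternatives covered background correction and normalization, the dim-probe filter, probe averaging, slide and replicate blocks, a fit of all 24 arrays, the genotype characteristic, and each array left out. Arrays were taken to have Y-linked transcripts where the mean of Ddx3y and Eif2s3y was above the array's 75th percentile. Alternatives on Y-linked transcripts, an Esr1 probe, the sex chromosomes, the percentile over detected probes and single slides were added after seeing the data.

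Arrays lie on 4 slides. Slide 1 holds all wild-type arrays of 16 h and Top2b-deleted PBS replicates 1 and 2. Slide 2 holds the other 4 arrays of 16 h. Slide 3 holds replicates 2 and 3 of every group of 72 h, and slide 4 holds replicate 4. Whether replicate numbers pair the arrays was checked by correlating the deviations of same-numbered arrays from their group means. Every pair was over 0.1 for Top2b-deleted doxorubicin against PBS at 16 h (lowest r 0.12) and at 72 h (lowest r 0.27) and for the genotypes in PBS at 72 h (lowest r 0.35). The pairing is inferred from these values, since the labels do not say what a replicate number shares. At 72 h same-numbered arrays also share a slide.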

Results

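The series profiled cardiomyocytes of wild-type mice and of mice with Top2b, the gene of DNA topoisomerase II beta, deleted in cardiomyocytes, after doxorubicin or PBS. Doxorubicin is an anthracycline that poisons type II topoisomerases. There were 3 arrays in each of 8 groups: wild type or Top2b-deleted, PBS or doxorubicin, and 16 h or 72 h. The 75th percentile of processed signal ranged from 146 to 282 over the 24 arrays. The labels give all mice as male and 6 weeks old. The Y-linked gene Ddx3y was well above background on 7 arrays, where Eif2s3y was at least 3.05, and these are called arrays with Y-linked transcripts. The other 17 had Xist well above background. On them Eif2s3y was at most -1.36, though well above background on 12, and Uty was well above background on 1, Top2b-deleted PBS replicate 1 of 16 h. The 7 arrays were 3 of 3 wild-type PBS arrays at 16 h, 1 wild-type and 1 Top2b-deleted doxorubicin array at 16 h, and 1 wild-type and 1 Top2b-deleted PBS array at 72 h.

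The targeted gene was compared first. The Top2b probe (mm9, chromosome 14, 17263157 to 17263216) was lower on every Top2b-deleted array than on any wild-type array at both times. At 16 h its log2 level was 4.2 ± 0.16 (SD, n = 6) in wild type and 2.99 ± 0.28 (SD, n = 6) in Top2b-deleted arrays, a difference of -1.22, or 43% of wild type (exact permutation p = 0.00216, two-sided). At 72 h the levels were 3.43 ± 0.17 and 2.51 ± 0.34 (SD, n = 6 each), a difference of -0.92, or 53% of wild type (exact permutation p = 0.00216, two-sided). Whether the probe lies inside the deleted part is not given in the sources used here. Grouped by the genotype characteristic in place of the titles, the 16 h difference was -0.26 (exact permutation p = 0.511), and 0 genes passed in limma for wild-type doxorubicin against PBS and for the genotypes in PBS at 16 h. Top1 did not pass in any comparison, for example at 0.36 ± 0.16 (adjusted p = 0.119) in wild type after doxorubicin at 16 h.

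**Figure D1:**
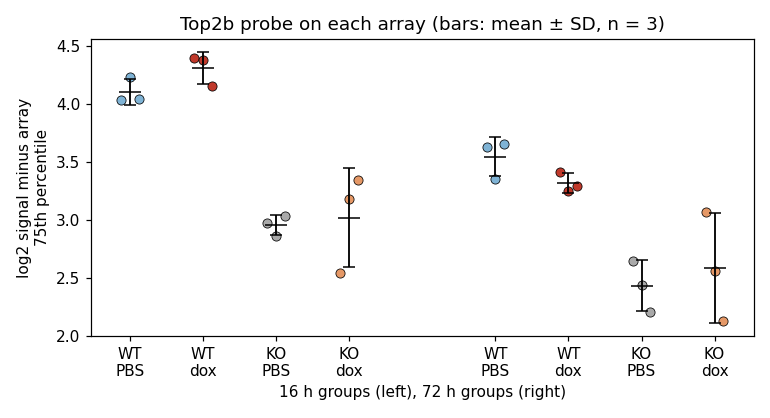
Top2b probe signal on each array (log2, minus the array's 75th percentile) for the 4 groups at 16 h and at 72 h. Points are arrays and bars are mean ± SD of 3 arrays; the highest Top2b-deleted value at 16 h was 3.34 and the lowest wild-type value 4.03.

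The question of the next comparison was which transcripts doxorubicin changed within 16 h in wild-type cardiomyocytes. Of 18750 genes, 5202 passed the threshold, 2566 higher and 2636 lower, and 2310 of them changed at least 2-fold. The groups differ in more than the drug, since all 3 PBS arrays and 1 doxorubicin array have Ddx3y signal. An Esr1 probe was at background on the PBS arrays and above it on doxorubicin replicates 2 and 3 (0.6 and 1.05). With Y-linked transcripts as a covariate 151 of 164 named calls kept their side of the threshold. The Esr1 probe as a covariate is no separate check. Within a group of 16 h it varies only among wild-type doxorubicin arrays, where it is the reverse of the Y-linked division. The wild-type effect then rests on doxorubicin replicate 1 against PBS. The largest rise among genes measured on every array was in Hmox1, the haem-degrading heme oxygenase 1, at 5.63 ± 0.47 (49.6-fold, adjusted p = 6.09e-05). Rises followed in Slc10a6 (4.79 ± 0.88), Spc25, a kinetochore protein (4.11 ± 0.28), Pnpla3 (3.94 ± 0.77), the interferon-inducible GTPases Igtp (3.69 ± 0.92) and Irgm2 (3.37 ± 0.91), the activin subunit Inhbb (3.59 ± 0.99), Trp53inp1 (3.53 ± 0.39), Pnmt, which makes adrenaline (3.46 ± 0.20), and Apod (3.44 ± 0.31). The largest falls were in the transferrin receptor Tfrc (-4.87 ± 0.47, adjusted p = 0.000105) and Nppb, which encodes brain natriuretic peptide (-4.19 ± 0.76). Arhgef19 (-3.95 ± 0.89), Lingo3 (-3.88 ± 0.46), Rcor2 (-3.77 ± 0.33), Tnfaip2 (-3.67 ± 0.28), Lrrc4b (-3.37 ± 0.34), Pde4a (-3.35 ± 0.42), Wnt5b (-3.30 ± 0.19) and Ephb1 (-3.30 ± 0.77) fell as well. Saa3 was at least 36.8-fold, Gtse1 at least 18.4-fold and Serpina3g at least 14.2-fold higher. St8sia5 was at least 6.73-fold, Slc46a2 at least 5.93-fold and Fam163b at least 5.76-fold lower.

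Targets of p53 rose together in wild type at 16 h: 25 of 35 rose and 0 fell, with 25 and 0 adjusted over the list alone. Among them were the cell cycle inhibitor Cdkn1a (3.09 ± 0.41), the pro-apoptotic Bax (1.56 ± 0.10), Phlda3 (3.1 ± 0.23), Ckap2, which was below background in PBS, and the p53 ligase Mdm2 (1.03 ± 0.14, chosen after its value was seen). The list median was 1.50 (adjusted p = 2.15e-12, and 0.026 with an estimated correlation). Interferon response genes rose in 29 of 31 cases, 30 adjusted over the list alone, including the peptide transporter Tap1 (3.88 ± 0.38), Oasl1 (3.15 ± 0.41) and Ifit2 (2.81 ± 0.28). Their median was 1.98 (adjusted p = 6.71e-14, and adjusted p = 0.572 with an estimated correlation). Neutrophil markers moved with them: S100a9 (4.2 ± 0.72) and Ly6g (1.85 ± 0.29) rose, as did S100a8 from below background, 3 of 7 markers and 4 adjusted over the list alone, at medians of 4.59, 1.79 and 0.52 on the 3 arrays. The marker list median was 1.93 (adjusted p = 0.014, and adjusted p = 0.663 with an estimated correlation).

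Calcium handling and conduction genes fell in 22 of 31 cases and rose in 0, with the same counts adjusted over the list alone. The calcium channel subunit Cacnb2 fell (-2.03 ± 0.14), as did the dyad protein Jph2 (-1.89 ± 0.21), the potassium channel Kcnq1 (-1.66 ± 0.19) and calsequestrin Casq2 (-1.07 ± 0.14). The list median was -0.89 (adjusted p = 2.1e-09, and adjusted p = 0.156 with an estimated correlation). Of 24 sarcomere genes 6 fell, by either adjustment, including Csrp3 (-1.50 ± 0.15), at a median of -0.22 (adjusted p = 0.00847, and adjusted p = 0.663 with an estimated correlation). Regulators of mitochondrial biogenesis fell in 12 and rose in 2 of 29 cases, or 13 and 3 adjusted over the list alone, with Mfn1 at -1.21 ± 0.11 and Esrrg at -1.33 ± 0.24 (median -0.35, adjusted p = 0.016, and adjusted p = 0.705 with an estimated correlation). Subunits and assembly factors of electron transport complexes II to IV fell in 8 of 34 cases, 7 adjusted over the list alone, with Cox6a1 at -1.33 ± 0.19 (median -0.15, adjusted p = 0.0066, and adjusted p = 0.763 with an estimated correlation). In complex I, 3 of 37 genes fell and 0 did so adjusted over the list alone (median -0.14, adjusted p = 0.0187, and adjusted p = 0.827 with an estimated correlation).

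Antioxidant defence genes rose in 13 of 30 cases, among them Gclm (1.87 ± 0.20) and Txnrd1 (1.63 ± 0.27), with 13 higher and 1 lower adjusted over the list alone (median 0.30, adjusted p = 0.00244, and adjusted p = 0.572 with an estimated correlation). Glucocorticoid and fasting genes rose in 10 and fell in 1 of 25 cases, by either adjustment, led by Fkbp5 (3.14 ± 0.44) and Zbtb16 (2.80 ± 0.37), at a median of 0.89 (adjusted p = 0.000641, and adjusted p = 0.572 with an estimated correlation). Ribosome biogenesis genes rose in 17 and fell in 2 of 39 cases, 21 and 2 adjusted over the list alone, with Gnl3 at 1.04 ± 0.14 and Rrn3, an initiation factor of RNA polymerase I, at -1.08 ± 0.13 (median 0.36, adjusted p = 0.000303, and adjusted p = 0.663 with an estimated correlation). Fibroblast markers fell in 7 of 21 cases, such as Col3a1 (-2.74 ± 0.32), with 7 lower and 1 higher adjusted over the list alone (median -0.48, adjusted p = 0.0311, and adjusted p = 0.787 with an estimated correlation). Smooth muscle and pericyte markers fell in 6 of 16 cases, by either adjustment, such as Acta2 (-2.30 ± 0.30; median -0.79, adjusted p = 0.00689, and adjusted p = 0.617 with an estimated correlation). All 6 wild-type arrays of 16 h lie on slide 1, so neither a slide block nor slide 1 alone can move the list medians. With the slide as a block 4591 genes passed, and within slide 1 3301 did. With arrays of 1 Y status only, where 1 wild-type doxorubicin array is left and is taken to vary like the others, 7872 passed.

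Other lists did not pass in wild type at 16 h, though single members did. The clock gene Per2 rose from below background and Nr1d1 fell (-1.51 ± 0.30), with 7 of 17 clock genes higher and 1 lower, or 7 and 2 adjusted over the list alone (adjusted p = 0.0745). The survival gene Bcl2l1 rose (2.29 ± 0.24) among apoptosis regulators, 7 of 32 higher and 6 lower (adjusted p = 0.465). DNA damage and repair genes had 5 of 37 higher and 6 lower (adjusted p = 0.446). Fetal and stress genes had 1 of 18 higher, Ctgf (2.16 ± 0.42), and 6 lower, such as Fhl2 (-1.58 ± 0.15; adjusted p = 0.0784). Immediate early genes had 6 of 22 higher, such as Klf6 (1.78 ± 0.28), and 0 lower (adjusted p = 0.0792). Ubiquitin and autophagy genes had 9 of 29 higher and 2 lower (adjusted p = 0.0763). Cell cycle genes had 5 of 29 higher and 1 lower (adjusted p = 0.22).

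The TCA cycle had 1 of 20 higher and 3 lower (adjusted p = 0.0641), and glycolysis 3 of 24 higher and 7 lower (adjusted p = 0.172). In fatty acid oxidation 0 of 29 passed in limma (adjusted p = 0.44), and in ATP synthase 0 of 16 (adjusted p = 0.333). Heat shock proteins had 3 of 19 lower (adjusted p = 0.172) and the integrated stress response 4 of 31 higher and 2 lower (adjusted p = 0.566). Matrix genes had 4 of 22 higher and 7 lower (adjusted p = 0.778), and inflammatory cytokines 6 of 19 higher and 3 lower (adjusted p = 0.13). Endothelial markers had 3 of 24 higher and 2 lower (adjusted p = 0.639), macrophage markers 3 of 21 higher and 1 lower (adjusted p = 0.244) and adipocyte markers 1 of 6 lower (adjusted p = 0.977). In limma 0 lymphocyte, erythroid, atrial or Schwann and mesothelial markers passed (adjusted p = 0.932, 0.919, 0.959 and 0.536).

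**Figure D2:**
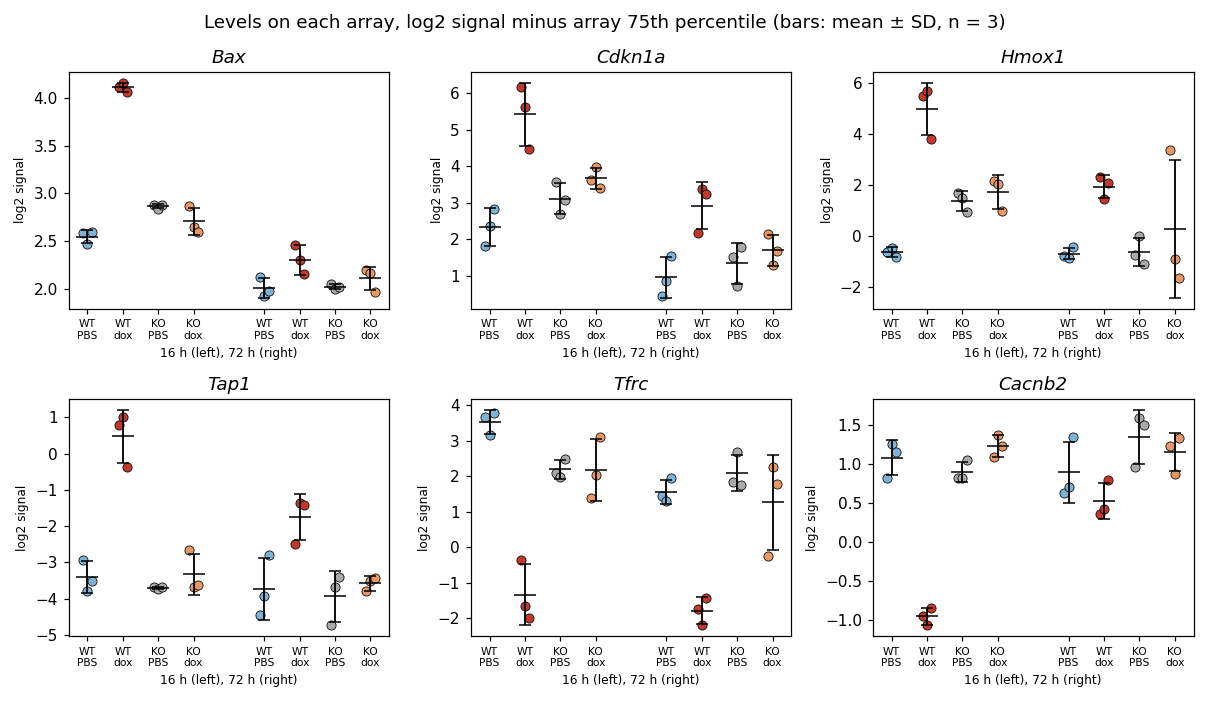
Levels of 6 genes on each array (log2 signal minus the array's 75th percentile) in the 4 groups at 16 h and 72 h. Points are arrays and bars are mean ± SD of 3 arrays; at 16 h the wild-type doxorubicin arrays stand apart for each gene, for Bax with an interaction of -1.72 and for Cacnb2 with 2.36.

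In Top2b-deleted cardiomyocytes at 16 h, doxorubicin changed 0 of 18750 genes past the threshold in limma, while 793 had an unadjusted p under 0.05. That is under the share of 0.05 that no change would give. The spread was shared with the wild-type groups, and whether this hid smaller changes was not tested. Bax was at -0.16 ± 0.10, Cdkn1a at 0.55 ± 0.41 and Hmox1 did not pass either. The median of p53 targets was 0.06 (adjusted p = 0.919). Macrophage markers were lower as a list, at a median of -0.70 (adjusted p = 6.7e-11, and adjusted p = 0.572 with an estimated correlation), with 0 of 21 genes past the threshold by either adjustment. Its value was -0.17 with the slide as a block (adjusted p = 0.129). Fibroblast markers had a median of -0.62 (adjusted p = 6.63e-08, and adjusted p = 0.663 with an estimated correlation) with 0 of 21 past the threshold by either adjustment, and -0.25 with the slide as a block (adjusted p = 0.0997). Interferon genes were higher as a list at a median of 0.29 (adjusted p = 0.00552, and adjusted p = 0.785 with an estimated correlation) with 0 of 31 past the threshold by either adjustment. The slide block gave 0.36 (adjusted p = 0.000638). Glucocorticoid and fasting genes had a median of 0.30 (adjusted p = 0.00342, and adjusted p = 0.617 with an estimated correlation) with 0 of 25 past the threshold and 1 higher adjusted over the list alone. The slide block gave 0.38 (adjusted p = 3.43e-05). Neutrophil markers were higher too, at a median of 0.20 (adjusted p = 0.0282), with 0 of 7 past the threshold and 2 higher adjusted over the list alone, and at 0.44 with the slide as a block (adjusted p = 0.0174). Other lists called lower were matrix genes (-0.40, adjusted p = 1.2e-07), endothelial markers (-0.29, 8.55e-05) and Schwann and mesothelial markers (-0.47, 0.00342). The slide block gave -0.20, -0.04 and -0.65 for them (adjusted p = 0.014, 0.936 and 0.000298). Fetal and stress (adjusted p = 0.003), cell cycle (0.00464), integrated stress response (0.00464), inflammatory cytokine (0.00986) and immediate early genes (0.049) were also lower as lists. The slide block gave adjusted p = 0.0364, 0.045, 0.00775, 0.601 and 0.782 for them. Fatty acid oxidation (adjusted p = 0.0121), mitochondrial biogenesis (0.0261) and DNA damage and repair genes (0.049) were higher, but did not pass with the slide as a block (adjusted p = 0.253, 0.576 and 0.376). Slide 2 holds all doxorubicin arrays of this comparison but only PBS replicate 3. Within it the spread comes from the doxorubicin arrays alone, so list calls there decide nothing. The slide-block values above rest on that same PBS array. Smooth muscle, lymphocyte, adipocyte and erythroid markers did not pass (adjusted p = 0.389, 0.207, 0.191 and 0.964). With an estimated correlation 0 of the 35 lists passed, the lowest adjusted p being 0.242. Counts with the slide as a block, within slide 2 and with the replicate block were 2, 0 and 0, and with arrays of 1 Y status, a fit with 1 wild-type doxorubicin array, 18.

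The difference between the genotypes' responses was then tested directly at 16 h. It passed for 2128 genes, 1146 with the response higher in Top2b-deleted arrays and 982 with it lower. The response was lower in Top2b-deleted arrays for Hmox1 (-5.29 ± 0.66), Spc25 (-4.40 ± 0.39), Phlda3 (-3.65 ± 0.32), the interleukin 6 receptor Il6ra (-3.61 ± 0.41) and Myc (-3.57 ± 0.78). It was higher in Top2b-deleted arrays, where doxorubicin changed 0 genes past the threshold in limma, for genes that fell in wild type: Tfrc (4.86 ± 0.67), Lingo3 (4.33 ± 0.65), Rcor2 (3.88 ± 0.46), Pde4a (3.64 ± 0.60) and Tnfaip2 (3.57 ± 0.40). The response of p53 targets was lower in 19 of 35 cases and higher in 0, with 23 and 0 adjusted over the list alone, at a median of -1.45 (adjusted p = 2.6e-12, and 0.026 with an estimated correlation). For calcium handling genes it was higher in 14 of 31, with 21 adjusted over the list alone (median 0.88, adjusted p = 3.52e-10, and adjusted p = 0.152 with an estimated correlation). Interferon genes had a lower response in 11 of 31, with 24 adjusted over the list alone (median -1.71, adjusted p = 2.14e-11, and adjusted p = 0.61 with an estimated correlation). Macrophage markers had a lower response in 4 of 21 cases, 6 adjusted over the list alone (median -1.02, adjusted p = 0.00116, and adjusted p = 0.743 with an estimated correlation), and a median of -0.47 with the slide as a block (adjusted p = 0.0828). Further lists with a lower response were ribosome biogenesis (adjusted p = 0.000775), antioxidant defence (0.00752), cell cycle (0.0164), glucocorticoid and fasting (0.0169), immediate early (0.0211), clock (0.0323) and inflammatory cytokine genes (0.0498). With an estimated correlation these were all lost (adjusted p = 0.572 to 0.721). Lists with a higher response were mitochondrial biogenesis (adjusted p = 0.00281), complexes II to IV (0.00389), complex I (0.0109), sarcomere (0.011), smooth muscle (0.0213) and TCA cycle genes (0.0224), all lost with an estimated correlation (adjusted p = 0.663 to 0.801). The slide block left 375 genes and medians of -1.42, 0.94 and -1.40 for the p53, calcium and interferon lists. The count was 4736 without wild-type doxorubicin replicate 3, 1262 and 1361 without wild-type PBS replicates 2 and 3, 1039, 1011 and 1358 without Top2b-deleted PBS replicates 1, 2 and 3, and 1102 and 1046 without Top2b-deleted doxorubicin replicates 2 and 3. No slide holds all 4 groups, so this comparison has no value within a slide.

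Over the 2431 genes past the threshold in the averaged comparison at 16 h (1306 higher and 1125 lower), the mean response was 1.34 in wild type and 0.169 in Top2b-deleted arrays. The difference was 1.17 (permutation p = 0.005, two-sided, the smallest that 400 assignments allow), and 97.1% of the genes had the larger response in wild type. It was 1.51 with the slide as a block (permutation p = 0.005), a correction that rests on 1 Top2b-deleted PBS array and whose uncertainty the p leaves out. Across genes the fold changes of the genotypes had a Pearson r of 0.06 and a Spearman rho of 0.013, where genes are not independent replicates. In the averaged comparison 53.7% of calls were higher, against 65.4% in the deposited value table, and 656 genes passed with the slide as a block. That count was 4332 without wild-type doxorubicin replicate 3, 1472 and 1616 without wild-type PBS replicates 2 and 3, 1389, 1393 and 1378 without Top2b-deleted PBS replicates 1, 2 and 3, and 1338 without Top2b-deleted doxorubicin replicate 2.

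**Figure D3:**
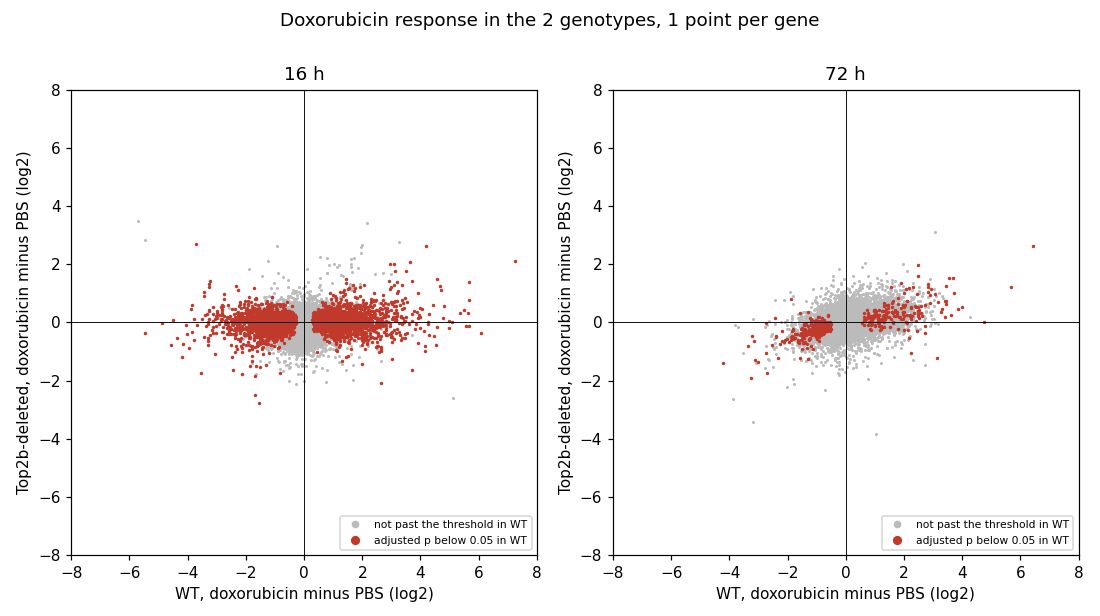
Doxorubicin minus PBS (log2 fold change) of each gene in wild type on the horizontal axis and in Top2b-deleted arrays on the vertical axis, at 16 h (left) and 72 h (right). Red points are genes past the threshold in wild type, 5202 at 16 h and 553 at 72 h; at 16 h they spread along the horizontal axis.

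Without the drug, Top2b-deleted and wild-type cardiomyocytes of the 16 h PBS arrays differed in 2320 genes, 1260 higher and 1060 lower in Top2b-deleted arrays. All 3 wild-type and 0 of the 3 Top2b-deleted arrays here have Ddx3y signal, so genotype and Y-linked status, and with it sex, cannot be told apart in this comparison. The largest rises were in Spink4 (5.76 ± 0.23), the stress cytokine Gdf15 (5.20 ± 1.23), Serpinb1a (5.15 ± 0.61), the activin subunit Inhba (4.83 ± 0.42), Cxcr6 (4.83 ± 0.81), Myh7, the slow myosin heavy chain (4.72 ± 0.72), Arc (4.71 ± 0.66), keratin Krt18 (4.66 ± 0.48), Itgb1bp3 (4.39 ± 0.44) and Wdfy1 (4.2 ± 0.16). The largest falls were in Scn4b, a sodium channel subunit (-4.66 ± 0.87), Arhgef19 (-4.2 ± 0.89), Cyfip2 (-4.11 ± 0.22), Spna1 (-3.74 ± 0.26), Pttg1 (-3.67 ± 0.16), Tmc7 (-3.65 ± 0.33), Fbxo44 (-3.55 ± 0.72), Meig1 (-3.55 ± 0.41), Scd4 (-3.51 ± 0.67) and Apln (-3.24 ± 0.48). Esr1 was at least 750-fold, Psca at least 14.8-fold and Pyroxd2 at least 10.6-fold higher, and 1 of 4 Esr1 probes carried that signal. That signal does not follow genotype throughout, since wild-type PBS replicates 2 and 3 of 72 h (8.41 and 8.58) were above every Top2b-deleted array (at most 7.1). Ankrd33b was at least 22.9-fold, Ogdhl at least 20.9-fold and Tmem52 at least 13.2-fold lower.

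Fetal and stress genes of the heart rose in 5 of 18 cases at 16 h in Top2b-deleted PBS arrays, with 10 higher and 1 lower adjusted over the list alone. They include Myh7, Gdf15, Ctgf (2.91 ± 0.42) and Nppa, atrial natriuretic peptide (2.44 ± 0.38), and the median was 1.13 (adjusted p = 0.000233, and adjusted p = 0.548 with an estimated correlation). Extracellular matrix genes rose in 9 and fell in 1 of 22 cases, 14 and 1 adjusted over the list alone, such as Thbs4 (3.31 ± 0.29) and Postn (2.82 ± 0.42; median 0.90, adjusted p = 1.2e-05, and adjusted p = 0.61 with an estimated correlation). Fibroblast markers rose beside them in 8 of 21 cases, 13 adjusted over the list alone, such as Mfap5 (1.85 ± 0.30; median 1.0, adjusted p = 3.17e-05, and adjusted p = 0.663 with an estimated correlation). Endothelial markers fell in 2 of 24 cases by either adjustment, Tie1 (-1.09 ± 0.23) and Emcn (-0.99 ± 0.23), at a median of -0.58 (adjusted p = 0.000133, and adjusted p = 0.668 with an estimated correlation). Fatty acid oxidation genes fell in 9 of 29 cases, 13 adjusted over the list alone, such as Hadh (-0.91 ± 0.15; median -0.36, adjusted p = 4.47e-06, and adjusted p = 0.663 with an estimated correlation). In the TCA cycle 5 of 20 genes fell, 7 adjusted over the list alone, such as Pdhb (-1.31 ± 0.22; median -0.33, adjusted p = 2.39e-06, and adjusted p = 0.663 with an estimated correlation). Complex I genes fell in 4 of 37 cases, 12 adjusted over the list alone (median -0.26, adjusted p = 9.91e-07, and adjusted p = 0.694 with an estimated correlation). The slide block left 1218 genes, and within slide 1, with 2 Top2b-deleted arrays, 769 passed. Either way the medians of the fetal, matrix, fibroblast, endothelial and fatty acid lists were 1.23, 1.01, 1.12, -0.45 and -0.39. The design fixes that they are the same, since only Top2b-deleted PBS lies on both slides, so this is 1 check. The count was 3817 without wild-type doxorubicin replicate 1, 1165, 1256 and 1349 without wild-type PBS replicates 1, 2 and 3, and 956, 1007 and 1218 without Top2b-deleted PBS replicates 1, 2 and 3.

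Immediate early genes rose in 5 of 22 cases in the same PBS arrays of 16 h, such as Jund (0.89 ± 0.11), with 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.00342, and adjusted p = 0.663 with an estimated correlation). Integrated stress response genes rose in 5 of 31 cases, 6 adjusted over the list alone, such as Psat1 (1.57 ± 0.34) and Nupr1 (1.40 ± 0.33; adjusted p = 0.00407, and adjusted p = 0.572 with an estimated correlation). Cell cycle genes rose in 5 of 29 cases, such as Kif20a (0.74 ± 0.15), with 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.00153, and adjusted p = 0.61 with an estimated correlation). Calcium handling genes fell in 4 of 31 cases by either adjustment, such as the calcium channel subunit Cacna2d1 (-0.88 ± 0.19; median -0.30, adjusted p = 0.00468, and adjusted p = 0.572 with an estimated correlation). In complexes II to IV 1 of 34 genes rose and 4 fell, 1 and 5 adjusted over the list alone (adjusted p = 2.44e-05, and adjusted p = 0.663 with an estimated correlation). Macrophage markers were higher as a list at a median of 0.61 with 0 of 21 past the threshold by either adjustment (adjusted p = 0.00972, and adjusted p = 0.785 with an estimated correlation), and at 0.87 with the slide as a block. Atrial markers did not pass as a list (adjusted p = 0.691), with Pam at 3.0 ± 0.18. Ribosome biogenesis genes were higher as a list (adjusted p = 0.00331) and ATP synthase lower (adjusted p = 0.00318), at adjusted p = 0.663 and 0.721 with an estimated correlation. Heat shock proteins (adjusted p = 0.0733), p53 targets (0.423) and DNA damage and repair genes (0.919) did not pass.

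At 72 h, doxorubicin changed 553 of 19669 genes in wild type, 196 higher and 357 lower. The largest rises were in Apod, a lipocalin (3.86 ± 0.50), Inmt (3.42 ± 0.78), the complement genes C4b (3.29 ± 0.56) and C3 (2.91 ± 0.58), Fmo2 (3.17 ± 0.68), Ephx1, epoxide hydrolase 1 (3.05 ± 0.46), Cyp26b1 (2.84 ± 0.53), Slc26a10 (2.72 ± 0.47), Irs2 (2.71 ± 0.45) and Gpr116 (2.59 ± 0.56). The largest falls were in the peptide hormone Apln (-4.21 ± 0.87), Tfrc (-3.35 ± 0.55), Rtn4r (-3.23 ± 0.55), Lingo3 (-3.02 ± 0.51), Ip6k3 (-2.40 ± 0.46), Igsf1 (-2.33 ± 0.43), Ddah1 (-2.26 ± 0.51), Tmem35 (-2.21 ± 0.41), Itga9 (-2.19 ± 0.41) and Cux2 (-2.13 ± 0.42). S100a8 was at least 12.3-fold, Mmp3 at least 6.81-fold and the complement factor Cfb at least 5.04-fold higher, and Cyp1a1 was at least 1.56-fold and Pak7 at least 1.52-fold lower. Of genes tested at both times, 98 rose and 222 fell at 16 h and at 72 h, where independent lists would share 24.1 and 49.8, and the fold changes had a Pearson r of 0.437 and a Spearman rho of 0.413 across genes.

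Interferon genes rose in 3 of 28 cases in wild type at 72 h, and in 20 adjusted over the list alone, such as Ifit2 (1.67 ± 0.31) and Irf7 (1.52 ± 0.29; median 1.32, adjusted p = 2.91e-13, and adjusted p = 0.572 with an estimated correlation). Immediate early genes rose in 3 of 22 cases, Nr4a1 (2.16 ± 0.48), Atf3 (2.23 ± 0.50) and, from below background in PBS, Egr2, and in 10 adjusted over the list alone (median 1.06, adjusted p = 1.01e-07, and adjusted p = 0.21 with an estimated correlation). Of 31 p53 targets 5 rose and 1 fell, 11 and 3 adjusted over the list alone, with Cdkn1a at 1.97 ± 0.41, Plk2 at 1.57 ± 0.21 and Gadd45a at -1.0 ± 0.18 (median 0.14, adjusted p = 0.00972, and adjusted p = 0.242 with an estimated correlation). Complex I genes were lower as a list with 0 of 37 past the threshold and 15 lower adjusted over the list alone (median -0.41, adjusted p = 4.33e-08, and adjusted p = 0.663 with an estimated correlation). Calcium handling genes fell in 2 of 31 cases, Kcnd2 (-1.68 ± 0.26) and Casq2 (-1.19 ± 0.25), and 16 adjusted over the list alone (median -0.51, adjusted p = 3.17e-05, and adjusted p = 0.572 with an estimated correlation). In the TCA cycle 3 of 20 genes fell, 7 adjusted over the list alone, such as Dlat (-0.98 ± 0.17; median -0.39, adjusted p = 0.00131, and adjusted p = 0.663 with an estimated correlation).

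Complexes II to IV fell in 2 of 34 cases, such as Cox11 (-0.97 ± 0.17), and in 12 adjusted over the list alone (median -0.37, adjusted p = 2.7e-06, and adjusted p = 0.663 with an estimated correlation). Mitochondrial biogenesis regulators fell in 3 of 29 cases, 9 adjusted over the list alone, such as Opa1 (-0.59 ± 0.12; adjusted p = 0.00049, and adjusted p = 0.663 with an estimated correlation). Heat shock proteins fell in 2 of 19 cases, 4 adjusted over the list alone, such as Hsph1 (-1.23 ± 0.28; adjusted p = 0.00421, and adjusted p = 0.663 with an estimated correlation). Amino acid and stress genes of the integrated stress response rose in 2 of 31 cases by either adjustment, Psat1 (2.25 ± 0.42) and, from below background in PBS, Fgf21, with adjusted p = 0.0334, and adjusted p = 0.663 with an estimated correlation. Fatty acid oxidation had 0 of 29 past the threshold (adjusted p = 0.706).

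Markers of other cell types moved with these groups at 72 h. Neutrophil markers rose in 3 of 9 cases, 6 adjusted over the list alone, at a median of 2.23 (adjusted p = 7.72e-06, and adjusted p = 0.21 with an estimated correlation). Endothelial markers had a median of 1.50 with 0 of 24 past the threshold by either adjustment (adjusted p = 2.41e-08, and adjusted p = 0.663 with an estimated correlation). Their medians were 0.97, 1.91 and 1.70 on the wild-type doxorubicin arrays and -0.71, -0.84 and 1.51 on the wild-type PBS arrays, the last from slide 4. Macrophage markers had a median of 0.94 with 0 of 20 past the threshold by either adjustment (adjusted p = 0.00972, and adjusted p = 0.787 with an estimated correlation), and erythroid markers one of -2.0 (adjusted p = 0.0737). With the slide as a block 2660 genes passed, with the replicate number as a block 3305, and within slide 3, with 2 arrays per group, 793. Within slide 3 the interferon, immediate early, complex I and endothelial medians were 1.49, 1.16, -0.59 and 2.24. The slide block itself cannot move the medians, since all groups of 72 h are spread alike over slides 3 and 4. The share of calls that were higher was 35.4%, against 15.4% in the deposited value table and 59.4% with the percentile over detected probes.

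The 72 h count in wild type rests on few arrays. It was 3, 1 and 1563 without wild-type PBS replicates 2, 3 and 4, and 1240, 1 and 32 without wild-type doxorubicin replicates 2, 3 and 4. It was 113, 76 and 258 without Top2b-deleted PBS replicates 2, 3 and 4, and 854, 312 and 264 without Top2b-deleted doxorubicin replicates 2, 3 and 4.

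**Figure D4:**
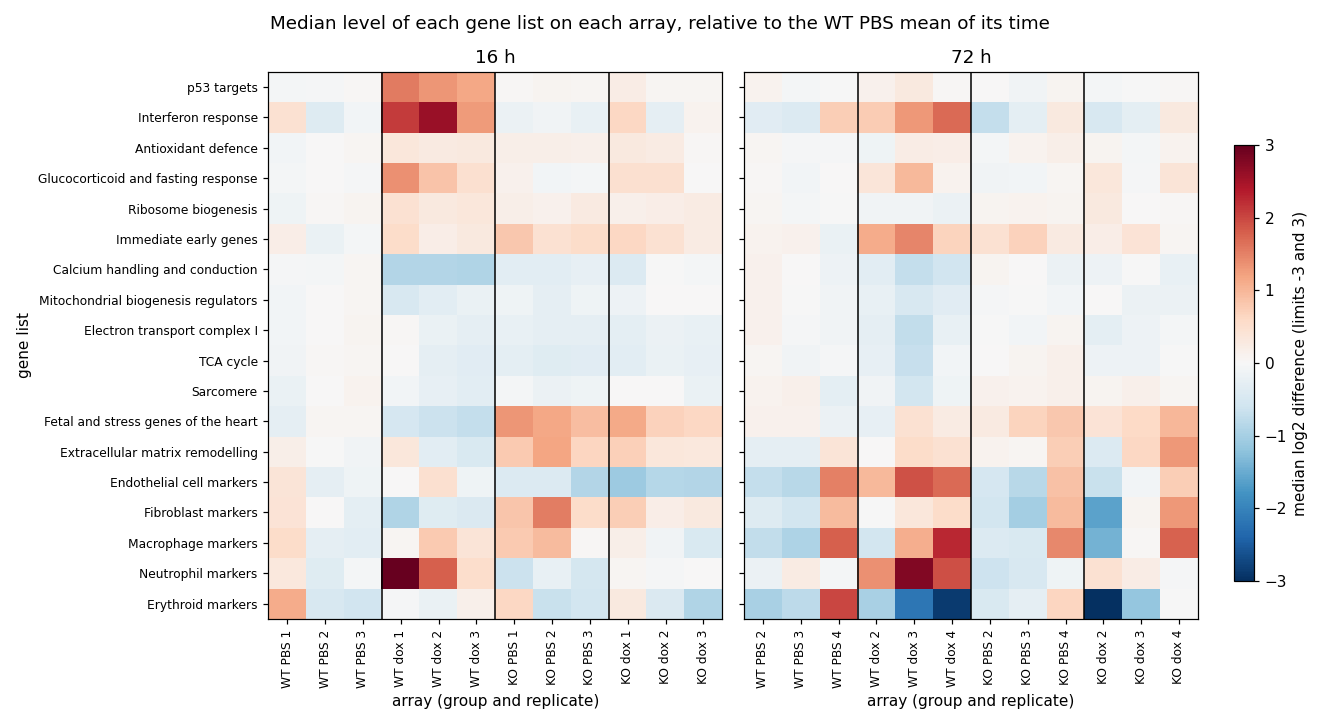
Median log2 level of 18 gene lists (rows) on each of the 24 arrays (columns, by group and replicate), relative to the wild-type PBS mean of the same time, with colours limited to 3 in either direction. On the 16 h wild-type doxorubicin arrays the p53 target medians were 1.56, 1.32 and 1.16; the neutrophil median of 4.59 at 16 h and the erythroid median of -3.15 at 72 h lie beyond the colour scale.

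In Top2b-deleted arrays at 72 h, 0 of 19669 genes passed for doxorubicin against PBS in limma, and 431 had an unadjusted p under 0.05. That is again under the share of 0.05 that no change would give, with the spread shared with the wild-type groups. The doxorubicin arrays were uneven. Replicate 2 was at 3.37 for Hmox1 and -0.25 for Tfrc, against -0.9 and -1.65, and 2.27 and 1.79, on replicates 3 and 4. The highest wild-type doxorubicin array of 72 h was at 2.3 for Hmox1. For Bax (2.2, against 2.16 and 1.97) and Cacnb2 (1.23, against 0.87 and 1.33) replicate 2 did not stand apart. These genes could show little, since in wild type at 72 h Bax was at 2.46, 2.3 and 2.15 after doxorubicin and 2.12, 1.92 and 1.98 after PBS. For Cdkn1a replicate 2 was at 2.14, against 1.29 and 1.67, and its PBS array was at 1.52. Its Top2b signal (3.07) was the highest of the Top2b-deleted arrays of 72 h, where the lowest wild-type value was 3.25. Complex I genes were lower as a list at a median of -0.15 (adjusted p = 1.13e-06, and adjusted p = 0.705 with an estimated correlation), and erythroid markers at -1.53 (adjusted p = 0.00242, and adjusted p = 0.572 with an estimated correlation), each with 0 members past the threshold by either adjustment. Interferon genes had a median of 0.06 (adjusted p = 0.691). Further lists called lower were complexes II to IV (adjusted p = 5.47e-07), the TCA cycle (0.000775), heat shock proteins (0.00354), ATP synthase (0.00468), immediate early (0.011) and cell cycle genes (0.0115), all lost with an estimated correlation (adjusted p = 0.633 to 0.763). Neutrophil (adjusted p = 0.0117) and adipocyte markers (0.0157) and glucocorticoid and fasting genes (0.0186) were higher, and were lost with an estimated correlation (adjusted p = 0.572, 0.572 and 0.61). The difference between the genotypes' responses passed for 0 genes in limma, with 1386 at an unadjusted p under 0.05. As a list, the response of immediate early genes was lower in Top2b-deleted arrays (median -1.37, adjusted p = 2.89e-12, and adjusted p = 0.113 with an estimated correlation), as was that of interferon genes (median -1.27, adjusted p = 1.96e-14, and adjusted p = 0.572 with an estimated correlation). Adjusted over the list alone, 8 of 22 and 2 of 28 members passed, all with a lower response. Among cell type lists the response was lower for endothelial (adjusted p = 4.09e-08), neutrophil (3.24e-05), macrophage (0.00425), atrial (0.0193) and Schwann and mesothelial markers (0.0348). All were lost with an estimated correlation (adjusted p = 0.663, 0.242, 0.785, 0.572 and 0.663). Of the 553 genes called in wild type, 89.3% moved the same way in Top2b-deleted arrays, and the Pearson r across genes was 0.404.

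The averaged comparison at 72 h passed for 47 genes, 27 higher and 20 lower. That is 57.4% higher, against 26.9% with normexp and quantile normalization, 16.5% in the deposited value table and 76.2% with the percentile over detected probes. Over the 47 genes, the mean response was 2.14 in wild type and 0.76 in Top2b-deleted arrays, a difference of 1.38 (permutation p = 0.005, two-sided). The replicate number as a block gave 1047 genes. With the slide as a block 859 genes passed and the difference was 0.881 (permutation p = 0.015). Within slide 3 there were 168 genes and a difference of 1.43 (permutation p = 0.0556). It was 0.443 over 2 genes (permutation p = 0.325) without Top2b-deleted PBS replicate 2. It was 0.392 over 16 genes (permutation p = 0.355) without Top2b-deleted doxorubicin replicate 4. Without Top2b-deleted PBS replicate 4, where 0 genes passed in limma, it was 0.858 (permutation p = 0.055) over the 200 genes with the smallest p. The count of 47 was 561 without wild-type doxorubicin replicate 2 and 105 without wild-type PBS replicate 4. It was 2 without wild-type PBS replicate 2 or Top2b-deleted PBS replicate 2, 13 and 16 without Top2b-deleted doxorubicin replicates 2 and 4, and 0 without replicate 3 of wild-type PBS, wild-type doxorubicin or Top2b-deleted PBS, or replicate 4 of wild-type doxorubicin or Top2b-deleted PBS.

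In the PBS arrays of 72 h, 423 genes differed between the genotypes, 210 higher and 213 lower in Top2b-deleted arrays. Spink4 (4.65 ± 0.70), Nppa (3.72 ± 0.59), Trnp1 (3.59 ± 0.30), Wdr92 (3.55 ± 0.44), Plagl1 (3.30 ± 0.50), Pdlim3 (3.19 ± 0.29), Tmem51 (3.04 ± 0.23), Gcnt1 (3.01 ± 0.28), Pygl, liver glycogen phosphorylase (2.95 ± 0.28), and Bex1 (2.83 ± 0.20) rose most. Scn4b (-5.57 ± 0.31), Fbxo44 (-4.44 ± 0.29), Arhgef19 (-4.05 ± 0.61), Pttg1 (-3.97 ± 0.28), Pdzd3 (-3.35 ± 0.48), Cdh4 (-3.34 ± 0.49), Cyfip2 (-3.31 ± 0.29) and Stbd1 (-3.15 ± 0.48) were among the genes that fell most. Rab6b was at least 51.3-fold, Il15 at least 20.6-fold and Ogdhl at least 11.5-fold lower, and Lpar3 at least 5.86-fold, Masp1 at least 3.17-fold and Tnni1, slow skeletal troponin I, at least 3.14-fold higher. Fetal and stress genes rose in 2 of 18 cases, Nppa and Ctgf (2.38 ± 0.41), with 4 adjusted over the list alone (median 0.56, adjusted p = 0.000591, and adjusted p = 0.572 with an estimated correlation). Between 16 h and 72 h, 133 genes were higher and 106 lower in Top2b-deleted arrays at both times, where independent lists would share 13.1 and 10, with a Pearson r of 0.65 and a Spearman rho of 0.522 across genes. Adding the slide as a block gave 793 genes and within slide 3 there were 612, where the median of the fetal and stress list was 0.33. With the replicate number as a block 910 passed, and every same-numbered pair had a correlation over 0.1. The count was 221, 210 and 680 without wild-type PBS replicates 2, 3 and 4, and 218 and 209 without Top2b-deleted PBS replicates 2 and 3.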

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

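The slide block and the splits were planned, and the tests of Y-linked status and of titles were chosen only after the results were seen. All bounds for these tests were written after the results were seen.

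Doxorubicin responses that differed between wild-type and Top2b-deleted arrays, by a test of the difference itself, are listed here. At 16 h 2128 genes passed for that difference. The largest per direction were Tfrc (4.86), Lingo3 (4.33), Rcor2 (3.88), Pde4a (3.64) and Tnfaip2 (3.57), and Hmox1 (-5.29), Spc25 (-4.40), Phlda3 (-3.65), Il6ra (-3.61) and Myc (-3.57). The mean response over genes of the averaged comparison was larger in wild type by 1.17 at 16 h and by 1.38 at 72 h. At 72 h it was 0.392 (permutation p = 0.355) without Top2b-deleted doxorubicin replicate 4, 0.443 (permutation p = 0.325) without Top2b-deleted PBS replicate 2, and 0.881 (permutation p = 0.015) with the slide as a block.

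The smaller response of Top2b-deleted arrays at 16 h was weighed against technical causes, with the mean response of each doxorubicin array taken against the PBS arrays of its genotype. It was 1.43 with Ddx3y signal and 1.42 and 1.17 without in wild type, and 0.22 with and 0.19 and 0.1 without in Top2b-deleted arrays. The difference of at least 0.98 within a Y status cannot exclude Y-linked status. All wild-type and 0 Top2b-deleted PBS arrays of 16 h have that signal, so the difference carries the same offset in either status. Within a genotype, doxorubicin arrays with and without it lay close together, but only 1 per genotype has it. With the slide as a block the difference was 1.51 (permutation p = 0.005). This cannot exclude slide, since 1 Top2b-deleted PBS array on slide 2 carries that correction. The correction was made before the permutation, so the p leaves out its uncertainty. Wrong titles are argued against by 18 probes with separate signal levels that divide all 24 arrays by title genotype without exception, where the genotype characteristic has 0. Against that, 4 probes on chromosome 4 follow the titles except on Top2b-deleted PBS replicate 3, 1 of the arrays with disagreeing labels. Its Top2b signal was 3.03, where the lowest wild-type value of 16 h was 4.03. Any difference between the mouse lines other than Top2b, and how much drug reached each heart, stay open and untested, and Y-linked status and slide stay open too. A lower response through the loss of Top2b is therefore a hypothesis, found and tested on the same data.

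Other assignments of the arrays were also fitted, over genes measured on all 12 arrays of a time. For the difference of responses at 16 h, 1 of 100 drawn assignments, the real one, gave as many as 2128 genes, the next highest gave 1, and chance is excluded. For the averaged comparison at 16 h, 1 of 100 gave as many as 2431, the next highest gave 773, and chance is excluded. These assignments also break the treatment and genotype effects and ignore the slide, with which the difference of responses passes for 375 genes, so they exclude only that no factor matters. For the difference of responses at 72 h the real count is 0 in limma (1386 at an unadjusted p under 0.05), so all 100 gave as many, and the highest was 502. For the averaged comparison at 72 h, 2 of 100 gave as many as 47, a share under 0.05, but another assignment gave 1178, which points to a structure of the samples.

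The 6 arrays of a comparison of 3 and 3 make 10 splits, too few for a share under 0.05. For doxorubicin in wild type the real value was 5199 at 16 h, with 1 as the highest other, and 552 at 72 h, with 19 as the highest other. For doxorubicin in Top2b-deleted arrays the real value was 0 in limma at 16 h (793 at an unadjusted p under 0.05), with 1 as the highest other, and 0 at 72 h (431), with 2 as the highest other. For genotype in PBS the real value was 2319 at 16 h and 418 at 72 h, with 0 as the highest other at either time.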

How the results depend on the processing

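The covariates, the single Y status, the sex chromosomes left out, the percentile over detected probes and the single slides were chosen only after the data were seen. In what follows, WT and KO stand for wild-type and Top2b-deleted arrays, interaction for the difference of responses and averaged for doxorubicin against PBS over both genotypes. Where a value moved, the cause was not tested unless stated.

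At 16 h, with 5202 genes for WT doxorubicin, 0 for KO doxorubicin (limma, 793 at an unadjusted p under 0.05), 2320 for genotype in PBS, 2128 for the interaction and 2431 averaged, the following moved by over 1.5 times. With no filter on dim probes genotype had 1273, the interaction 977 and averaged 1229. Under the slide block KO doxorubicin had 2, genotype 1218, the interaction 375 and averaged 656. All 24 arrays in one fit gave 1 for KO doxorubicin. With groups by the genotype characteristic these were 0, 1, 0, 0 and 1 in the order above, response size reversed to -0.327 (permutation p = 0.36, against 1.17) and Top2b was -0.26 (exact p = 0.511). Without the 4 arrays whose labels disagree KO doxorubicin had 1, genotype 1454, the interaction 1152 and averaged 1126, and response size was 1.27 with p = 0.0556, the smallest that the remaining permutations allow. The Y-linked covariate gave 1 for KO doxorubicin. The Esr1 covariate gave 1 for KO doxorubicin, 4648 for the interaction and 4432 averaged. Arrays of 1 Y status gave 7872 for WT doxorubicin, 18 for KO doxorubicin, 6504 for the interaction and 6124 averaged, but 1 WT doxorubicin array is left, taken to vary like the others, and then all WT and 0 KO arrays have Ddx3y signal. Slide 1 only gave 3301 for WT doxorubicin and 769 for genotype, with fewer arrays.

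At 72 h, with 553 genes for WT doxorubicin, 423 for genotype, 0 for the interaction (limma, 1386 at an unadjusted p under 0.05) and 47 averaged, normexp with quantile normalization gave 991 for WT doxorubicin, 1 for the interaction and 108 averaged, and quantile normalization 26 averaged. The deposited value table gave 968 and 272 averaged. With no filter on dim probes WT doxorubicin had 23 and averaged 0. With the slide as a block WT doxorubicin had 2660, genotype 793 and averaged 859. All 24 arrays in one fit gave 2430 and 1144 averaged, and moderation with trend and robust settings 953 and 128 averaged. The Y-linked covariate gave 22 and 0 averaged, and the Esr1 covariate 195, with 736 for genotype and 31 averaged. Arrays of 1 Y status gave 253 for genotype, 2 for the interaction and 2 averaged, and response size 1.74 over 2 genes with permutation p = 0.333, against 1.38. The percentile over detected probes gave 21 averaged, and slide 3 only 168 averaged and response size 1.43 with permutation p = 0.0556. KO doxorubicin at 72 h had 0 genes in limma under every alternative run (431 at an unadjusted p under 0.05).

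With the replicate block, 72 h WT doxorubicin had 3305 genes, genotype 910 and averaged 1047. Same-numbered arrays correlate for genotype in PBS at 72 h, so 910 stands beside 423. For WT doxorubicin the r values were 0, 0.41 and 0.48, and same-numbered arrays of 72 h also share a slide. KO doxorubicin had 0 genes at either time with the replicate block, and the block moved no other count by over 1.5 times.

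Leaving out each array in turn gave, at 16 h, 3630 to 6650 for WT doxorubicin, 0 to 2 for KO doxorubicin, 956 to 3817 for genotype, 1011 to 4736 for the interaction, 1338 to 4332 averaged, 1.02 to 1.37 for response size and -1.29 to -1.13 for Top2b. At 72 h it gave 1 to 1563, 0 to 0, 209 to 680, 0 to 3, 0 to 561, 0.392 to 1.85 and -1.03 to -0.84 in the same order. List calls were 103 to 125 in total, against 114; of 61 at 16 h 50 to 58 still passed in the same direction, and of 53 at 72 h 42 to 52. Of the 114, 2 did with the estimated correlation, which allows for genes of a list that move together. Adding the slide as a block, 97 of the 114 list calls still passed in the same direction and 17 did not.

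Of 1218 calls or values of named genes, 1042 stayed on their side of the threshold with the slide as a block, 69 newly passed it and the others no longer did. With no filter on dim probes 1080 stayed and 138 were no longer past it, with more genes tested. Gdf15 for genotype in PBS at 16 h reversed to -0.018 with the Esr1 covariate, a probe well above background on every KO array. At 16 h that covariate is estimated only from differences among the WT doxorubicin arrays, so the reversal says nothing about Esr1. Signal over background limits dim genes, since only 42.9% to 52.6% of spots per array were well above it.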

Other observations

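The tests of haplotypes, probe variants, Y-linked status, cell share, slide 3 and Esr1 were chosen only after the results were seen. The bound for Esr1 was also changed after its value was seen.

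Without the drug, single members of lists that did not pass differed between Top2b-deleted and wild-type arrays. The atrial list had adjusted p = 0.691 at 16 h and 0.0737 at 72 h, and the Schwann and mesothelial list 0.954 and 0.516. Keratin 18 (Krt18) was higher in Top2b-deleted PBS arrays at 16 h and again at 72 h (2.72 ± 0.36), and the Schwann cell gene Sox10 was lower at 72 h (-1.45 ± 0.16). Pam, which amidates peptide hormones, was higher at 72 h (2.30 ± 0.22), and so was the matrix gene Thbs4 (1.51 ± 0.32). The clock gene Per2 had a lower doxorubicin response in Top2b-deleted arrays at 16 h (limma adjusted p = 0.00174) and was below background in wild-type PBS, and 5 of 17 clock genes had a lower response (list adjusted p = 0.0323, 0.0524 with the slide as a block and 0.572 with an estimated correlation). Each gene has 1 of the 4 smallest adjusted p-values of its list.

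Erythroid markers were uneven over the 72 h arrays. Their medians, relative to the wild-type PBS mean, were -0.97, -0.78 and 2.0 on wild-type PBS replicates 2, 3 and 4, and -0.97, -2.17 and -2.88 on wild-type doxorubicin replicates. On Top2b-deleted arrays they were -0.45, -0.28 and 0.65 for PBS and -3.15, -1.17 and -0.01 for doxorubicin.

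Genes that differed between the genotypes in PBS at both times, 239 in the same direction, were weighed against technical causes. At 72 h 1 PBS array per genotype has Ddx3y signal, so Y-linked status is balanced and does not separate the genotypes there. Without those arrays the median change was 1.74, against 1.74 over all arrays, and 239 of 239 kept their direction (119 stayed past the threshold in limma with 2 arrays per group). That adds no support, since the genes were chosen on these same arrays. At 16 h Y-linked status cannot be told apart from genotype. Haplotypes that differ between the mouse lines stay open: 71.5% of these genes had another such gene 0.1 to 5 Mb away, against 65.4% in random draws (permutation p = 0.045), while genes of the doxorubicin comparison had 78.4% against 74.8% (permutation p = 0.087). Sequence variants under probes stay open too: a separate probe showed under 0.25 of the change in 27.5% (19 of 69) of genes, against 17.8% (13 of 73) of doxorubicin genes (Fisher p = 0.228). A direct effect of Top2b is among the open explanations and cannot be told apart from line differences here.

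Endothelial markers were higher as a list in wild-type doxorubicin arrays at 72 h, with 0 of 24 genes past the threshold in limma, adjusted p = 0.663 with an estimated correlation, and 1 PBS array (1.51) above 1 doxorubicin array (0.97). A lower share of cardiomyocytes was taken to raise all other cell types alike, which is an assumption. The endothelial median minus the fibroblast (1.26, SE 0.33) and erythroid (3.63, SE 0.84) medians differed between doxorubicin and PBS with no overlap of arrays. Minus the smooth muscle (0.92, SE 0.43), macrophage (0.65, SE 0.62) and lymphocyte (1.56, SE 0.85) medians the arrays overlapped. Erythroid markers were uneven among the PBS arrays, and a drug effect on fibroblast markers themselves was not tested. The values go against an even rise of endothelial and fibroblast markers, but do not exclude a lower share of cardiomyocytes. Within slide 3, where slide does not vary, the endothelial difference was 2.22 with 2 arrays per group. On slide 4 it was 0.2 with 1 array per group, so the rise was not repeated there. The wild-type PBS array of slide 4 is also the only wild-type array of 72 h with Ddx3y signal (2.44), so slide and Y-linked status cannot be told apart for it. A change in endothelial cells themselves, in what is isolated with the cardiomyocytes, stays open and was not tested.

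A transgene that carries part of Esr1 was a hypothesis for the Esr1 signal on 1 probe. That probe was well above background on 12 of 12 Top2b-deleted arrays (5.04 to 7.1) and on 6 of 12 wild-type arrays. The wild-type arrays included PBS replicates 2 and 3 at 72 h (8.41 and 8.58) and doxorubicin replicates 2 and 3 at 16 h (0.6 and 1.05). The other 3 probes were well above background in 1 of 72 readings, on a wild-type doxorubicin array of 16 h. The first bound, 0 such readings, would have counted against the hypothesis. It was replaced, after the value was seen, by how many Top2b-deleted arrays show the other probes, and by that bound the test leaves the hypothesis open. With 1 of 72 readings, the other probes may not work at all. The labels name no transgene.

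Over the 24 arrays 92 probes had separate levels, with a gap of at least 1.5 and at least 3 arrays on either side. Of these 18, on 6 chromosomes, divided the arrays by title genotype, among them probes of Pttg1, Cyfip2, Wdfy1 and Rab6b. On chromosome 4, from 141 to 155.3 Mb, 4 probes divided the arrays by title genotype except that Top2b-deleted PBS replicate 3 of 16 h had the wild-type level. That array is 1 of the 4 whose genotype labels disagree. Ddx3y was at least 2.44 on the 7 arrays with Y-linked transcripts and at most -5.22 on the others, and Xist at most -5.52 and at least -2.38.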
